A study of Rattus norvegicus with 144 samples.

How the data were processed

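Rats had medial meniscus transection (MMT) in the right knee and a sham operation in the left. RNA came from cartilage, menisci and synovium of both knees at 2, 4 or 6 weeks. Per the labels, complementary DNA was made from total RNA with barcoded oligo-dT and template-switching primers of an early access kit, and libraries were pooled before amplification, so reads come mainly from polyadenylated transcripts. The submitters' processing notes name UMI-tools, Trim Galore 0.6.4, STAR 2.6.1d, featureCounts 1.6.4 and DESeq2 1.20.0 with the rat genome build Rnor_6.0. They give neither the order of the steps nor whether reads with 1 molecular identifier were collapsed, so intervals that rest on counts cover counting error only.

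The deposited gene table holds raw read counts made by the authors for 32545 Ensembl genes, all whole numbers, of which 21464 had at least 1 count. The authors also gave TPM (transcript shares scaled to a fixed total) for the same libraries, which were used only as an alternative unit, and the program that made them was not stated. An FPKM table was not used. Gene symbols are those in the deposited tables, 505 symbols belong to more than 1 gene, and identifiers rather than symbols were tested. Reads from genes of near-identical sequence, such as the globin genes, cannot be assigned to 1 copy from these tables. Genome positions were not analysed here. Of the 144 samples in the labels, 143 had a column, and the sham meniscus of rat 16 at 4 weeks was not analysed here. No column lay outside the labels.

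Libraries were grouped by tissue, surgery and week into 18 groups, with the rat as the replicate. Total counts ran from 256467 to 3936066 per library with a median of 1658369. For a share of counts in 1 library, Wilson intervals at the 95% level were computed with scipy 1.17.1 (numpy 2.4.6, pandas 2.3.3). A number at the start of each sample's description (2 to 6) was taken as a plate prefix. Its meaning is not stated, and prefix 3 alone spans 2 times (2 and 4 weeks). Each library was compared with the mean sham profile of the 3 tissues over the 500 genes that vary most between those profiles, and a total under 0.25 times the median of its tissue counted as low depth. No pair of libraries of the same group was a copy of another, since the lowest chi-square per degree of freedom between them was 3.36. Pairs across groups were not compared. The 2 knees of 1 animal are a pair, which was checked on the residuals after the group means: the median correlation was -0.02 to 0.258 between knees of the same rat and -0.13 to -0.001 between different rats, and 31 of 71 pairs were above 0.1.

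Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-tests with robust dispersion, trimmed mean of M-values scaling), with 1 coefficient per group and no term for the rat. Genes were kept with the edgeR expression filter (minimum count 10, minimum total 15), which left 10292 genes in cartilage, 10785 in meniscus, 10551 in synovium and 11788 in the fit of all tissues. Tests are two-sided, and p was adjusted by Benjamini and Hochberg within each comparison; a gene passed at an adjusted p under 0.05. Comparisons were MMT against sham in each tissue at each week, the difference of that effect among the 3 times within a tissue (an F-test), the difference of the effect averaged over times between tissues, and the difference between tissues in sham knees. CPM values use the scaled library sizes, fold changes are those of edgeR at its default prior count, and the direction per rat was read from log2 CPM with a prior count of 2. Errors beside a log2 fold change are standard errors taken as the change over the square root of its F, errors beside CPM or a share are standard deviations, and each group has 8 libraries except 7 for the sham meniscus at 4 weeks.

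Fixed before the data were examined were these comparisons, the test, most of the alternatives, 26 gene lists with 421 genes and the rule for the genes the text names. The lists were chondrocyte matrix, fibrous matrix, matrix proteases, protease inhibitors, mechanotransduction, inflammatory mediators, TGF-beta and BMP signalling, Wnt signalling, FoxO and autophagy, chondrocyte hypertrophy, proliferation, pain and neurotrophic factors, synovial fibroblast, macrophage, lymphocyte, neutrophil and marrow myeloid, erythroid, osteoblast and osteocyte, osteoclast, skeletal muscle, adipocyte, endothelium, pericyte and smooth muscle, Schwann cell, immediate early and heat shock, and mitochondrially encoded genes. Among the 13 list genes without a matching symbol were Snorc, Serpina3n, Nos2, Ccnb2, Nfatc1, Myh2, Myh4, Pecam1, Foxd3, Ier2, Mt-co3 and Mt-cyb. Lists were tested against the other genes with camera in limma 3.58.1 (preset correlation 0.01 on voom values, adjusted over all lists in a tissue and week), and again with a correlation estimated from the data. A list's members were also counted after adjustment over the list alone. Shares of counts in marker lists were compared between knees of 1 rat with an exact two-sided sign-flip test, 90 tests in all, whose smallest possible p with 8 pairs is 0.00781.

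Named genes were 20 core genes, the 4 genes with the largest and the 4 with the most negative change per tissue and week, the 4 members of each list and tissue with the smallest adjusted p at any week, and the 4 largest differences in each direction between tissues (8 by p for the time test). For the largest changes, a gene had to pass the test, average at least 10 CPM in a group and move the same way in at least 7 of 8 rats. Where a named gene is given at another week, its value there stands beside it. Some of these genes are not reported here.

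The alternatives fixed at that stage were relative log expression scaling, no filter, a filter on a mean of at least 10 counts, DESeq2 1.42.0, limma-voom with sample weights, the rat as a block (a factor in the same edgeR fit), the plate prefix as a covariate, leaving out rats 6 and 11 (whose libraries span 2 prefixes), leaving out low-depth libraries or libraries close to another tissue, the muscle list as a covariate, only the 16 libraries compared, and leaving out each rat in turn. The edgeR legacy setting is the default of this version and was not run apart. Added after seeing the data were the newer edgeR dispersion setting, leaving out the doubted libraries, leaving out the synovium library with the most muscle transcripts, and limma on log2(TPM + 1) of genes with a mean TPM of at least 1, also after removal of Mt-atp6. The power of each design was tested on simulated data with known fold changes. Figures were drawn with matplotlib 3.10.9.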

Results

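RNA from 3 knee tissues of 24 male Lewis rats was sequenced after medial meniscus transection (MMT), an operation that destabilises the joint and is used as a model of osteoarthritis. Each rat had MMT in the right knee and a sham operation in the left knee, in which the capsule was opened and the meniscus was left whole. Both knees of 8 rats each were sampled at 2, 4 and 6 weeks for cartilage, meniscus and synovium. This gives 18 groups of 8 libraries, but 7 sham menisci at 4 weeks (without rat 16). Per the labels, the synovium was thin and taken with some of the fat beneath it. Total counts ran from 280627 to 3856471 in cartilage (median 1919448.5, 48 libraries), from 820249 to 3469755 in meniscus (median 1636979, 47 libraries) and from 256467 to 3936066 in synovium (median 1593492, 48 libraries). At 8 rats per group and these depths, a gene simulated to change 2-fold was called in 61.2% of cases in cartilage, 69.2% in meniscus and 71.2% in synovium at 2 weeks. The simulation drew each gene on its own, without differences in tissue make-up between libraries, so real power can be lower where make-up varies. The muscle share of synovium ran from 0.0212 to 15.2% among sham libraries at 4 weeks.

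Of these libraries, 3 were in doubt. The sham cartilage of rat 6 at 2 weeks (280627 counts) and the sham synovium of rat 16 at 4 weeks (256467 counts) had a low depth. The sham cartilage of rat 16 at 4 weeks (886802 counts) correlated better with sham meniscus than with sham cartilage. Side of the body cannot be separated from surgery, since every MMT knee was a right knee. Leaving the doubted libraries out moved the cartilage counts to 196 at 2 weeks, 157 at 4 weeks and 217 at 6 weeks.

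**Figure D1:**
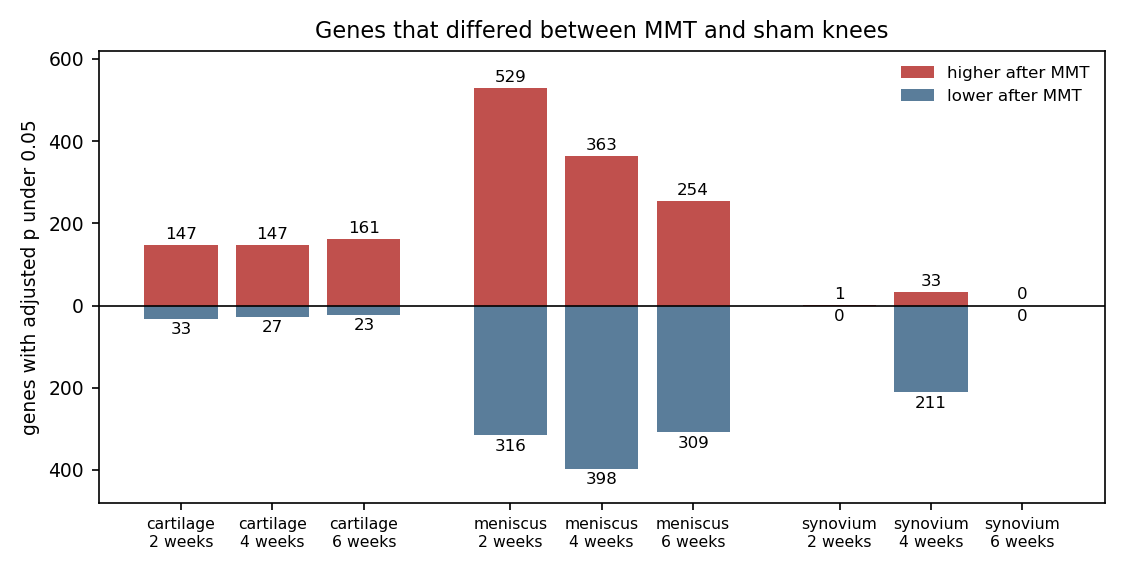
Bars give the number of genes with an adjusted p under 0.05 (edgeR, 8 rats per group, 7 sham menisci at 4 weeks) that were higher (red, upward) or lower (blue, downward) in MMT than in sham knees, per tissue and week. Meniscus had 845, 761 and 563 such genes at 2, 4 and 6 weeks, cartilage 180, 174 and 184, and synovium 1, 244 and 0.

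The first question is which genes of each tissue differed between the MMT and sham knee at each week. In cartilage, the genes of the secreted signals Il11, Ccl2 and Inhba were higher after MMT at each week. Il11 (ENSRNOG00000017386), a cytokine of the interleukin 6 family, averaged 1.47 ± 1.53 CPM in sham and 111.3 ± 36.3 CPM in MMT knees at 2 weeks. Its log2 change was 6.32 ± 0.53 at 2 weeks, 4.72 ± 0.49 at 4 weeks and 3.68 ± 0.46 at 6 weeks (adjusted p = 2.88e-11, 9.98e-09 and 5.51e-07), each time in 8 of 8 rats. Ccl2, a chemokine that attracts monocytes, rose by 3.27 ± 0.56, 3.23 ± 0.55 and 3.54 ± 0.54 (adjusted p = 0.000133, 9.99e-05 and 1.38e-05). Inhba, a subunit of the TGF-beta family ligand activin A, rose by 2.30 ± 0.28, 2.02 ± 0.28 and 2.14 ± 0.28 (adjusted p = 2.63e-07, 2.89e-06 and 1.28e-06).

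**Figure D2:**
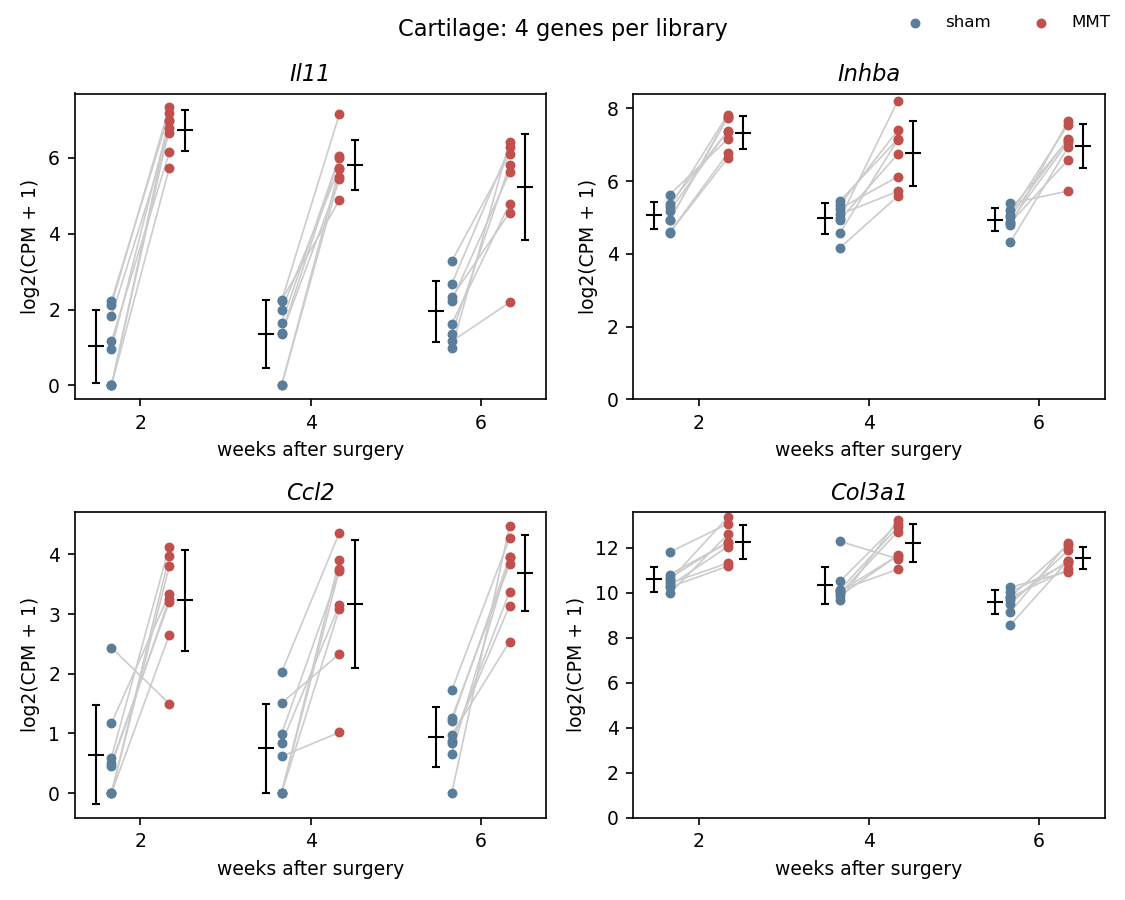
Each point is 1 cartilage library, as log2(CPM + 1) of Il11, Inhba, Ccl2 and Col3a1 against weeks after surgery. Sham is blue and MMT red, grey lines join the knees of 1 rat, and black marks give the mean and SD of each group (n = 8). Il11 was higher in the MMT knee of 8 of 8 rats at each week.

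In cartilage 180 genes passed at 2 weeks (147 higher and 33 lower), 174 at 4 weeks (147 and 27) and 184 at 6 weeks (161 and 23), by edgeR over 10292 genes. Of these, 76 rose and 11 fell at least 2-fold at 2 weeks, 62 and 15 at 4 weeks, and 74 and 9 at 6 weeks. Tnn, a tenascin of the extracellular matrix, had the largest change at 2 weeks (7.15 ± 1.12, adjusted p = 4.44e-05), from 0.376 ± 0.785 to 84 ± 76.7 CPM. It also led at 4 weeks (5.01 ± 0.99, adjusted p = 0.00165), and did not pass at 6 weeks (2.51 ± 0.85, adjusted p = 0.147). F3, the tissue factor that starts coagulation, rose by 3.49 ± 0.61 at 2 weeks (adjusted p = 0.000192). Pcsk5, a proprotein convertase, rose by 2.67 ± 0.28, 2.84 ± 0.27 and 2.64 ± 0.27 (adjusted p = 5.65e-09, 1.15e-09 and 6.29e-09). Hapln4, a protein that links hyaluronan and proteoglycan, rose by 2.72 ± 0.43 at 4 and 2.82 ± 0.43 at 6 weeks (adjusted p = 4.53e-05 and 1.87e-05). Reln, the secreted glycoprotein reelin, rose by 3.14 ± 0.76, 2.685 ± 0.702 and 3.27 ± 0.68 (adjusted p = 0.014, 0.0302 and 0.00241).

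Among the genes that fell in cartilage, Grem1, an antagonist of bone morphogenetic proteins, went from 1059 to 396.3 CPM at 2 weeks (-1.41 ± 0.28, adjusted p = 0.00196). Lect1, the cartilage protein chondromodulin, fell at 2 weeks (-1.74 ± 0.37, adjusted p = 0.00392). Myoc, which encodes myocilin, fell at 4 weeks (-1.55 ± 0.35, adjusted p = 0.00806) and 6 weeks (-1.87 ± 0.35, adjusted p = 0.000664). So did Dlk1, a Notch-related regulator of differentiation (-1.73 ± 0.34 and -1.62 ± 0.34, adjusted p = 0.00154 and 0.00249). Notum, an enzyme that inactivates Wnt proteins, changed by -1.62 ± 0.37 and -1.62 ± 0.36 (adjusted p = 0.00806 and 0.00539), up to 0.0546 without rat 13 and 0.0543 without rat 21. Cntfr, a receptor subunit for ciliary neurotrophic factor, changed by -1.52 ± 0.42, -1.65 ± 0.41 and -1.79 ± 0.41 (adjusted p = 0.0398, 0.0226 and 0.00832). It passed in 2, 5 and 7 of the 8 fits that left out 1 rat (highest adjusted p = 0.14 without rat 7, 0.107 without rat 13 and 0.0559 without rat 19).

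The fibrous matrix list, the collagens and glycoproteins of fibrous tissue, rose in cartilage at each week. Of its 22 measured genes 9, 8 and 9 were higher and none lower by edgeR at 2, 4 and 6 weeks, against 13 higher and 1 lower, 12 and 0, and 10 and 0 adjusted over the list alone. The camera test of the list gave an adjusted p of 3.61e-13, 1.15e-18 and 2.96e-12, and with an estimated correlation an adjusted p of 0.00363, 0.000854 and 0.00502. Col3a1, the collagen of loose and healing tissue, rose by 1.72 ± 0.36, 1.82 ± 0.36 and 1.95 ± 0.36 (adjusted p = 0.00353, 0.00159 and 0.000609). Fn1, fibronectin, rose by 1.21 ± 0.16, 1.30 ± 0.16 and 1.37 ± 0.16 (adjusted p = 6.83e-07, 4.01e-07 and 6.37e-08). Col5a1 rose by 1.12 ± 0.17, 1.24 ± 0.17 and 1.01 ± 0.17 (adjusted p = 1.36e-05, 2.75e-06 and 0.000108). Tnc, tenascin C, rose by 2.05 ± 0.51 at 2 weeks (adjusted p = 0.0216), a call kept in 5 of 8 fits that left out 1 rat (0.0981 without rat 1). Col1a1 (0.84 ± 0.86, adjusted p = 0.765) and Postn (2.17 ± 0.90, adjusted p = 0.287) did not pass at 2 weeks.

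The protease inhibitor list rose with it, with 5 of 9 genes higher at each week and 1 lower at 2 weeks. Adjusted over the list alone, 5 were higher and 2, 1 and 2 lower. The list's adjusted p was 1.42e-07, 2.23e-06 and 2.8e-05 (0.00134, 0.00225 and 0.00502 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, rose by 1.57 ± 0.17, 1.20 ± 0.17 and 0.89 ± 0.17 (adjusted p = 5.65e-09, 2.75e-06 and 0.000519), and Timp2 rose by 1.05 ± 0.13, 0.98 ± 0.13 and 0.95 ± 0.13. Of 16 matrix protease genes 3, 2 and 2 were higher and none lower (6, 4 and 4 adjusted over the list alone). The list's adjusted p was 0.00132, 0.00228 and 0.0524 (0.193 and 0.207 at 2 and 4 weeks with an estimated correlation). Htra1, a serine protease, rose by 1.11 ± 0.18 at 2 weeks (adjusted p = 4.83e-05), and passed at 4 and 6 weeks too (1.108 and 1.19). Mmp3, stromelysin 1, rose by 1.25 ± 0.24 at 4 weeks and 1.5 ± 0.24 at 6 weeks (adjusted p = 0.000791 and 5.06e-05). It had 0.75 ± 0.23 at 2 weeks (adjusted p = 0.0927, or 0.0111 with the rat as a block). Mmp13, the main collagenase of cartilage, did not pass (0.12 ± 0.70, -0.40 ± 0.69 and -1.17 ± 0.72, adjusted p = 0.983, 0.891 and 0.622).

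Of 10 inflammatory mediators measured in cartilage, 4 were higher at each week and none lower, also adjusted over the list alone. Camera gave the list an adjusted p of 0.000982, 0.000801 and 5.45e-05 (0.00363, 0.00245 and 0.00146 with an estimated correlation). On the TPM scale without Mt-atp6 the list's median at 4 weeks turned from 0.37 to -0.02. Besides Il11 and Ccl2, these were Tnfaip6, a hyaluronan-binding protein induced in inflammation (2.38 ± 0.30, 2.22 ± 0.30 and 2.23 ± 0.30), and the chemokine Cxcl14 (0.71 ± 0.12, 0.84 ± 0.12 and 1.17 ± 0.13). Il1b did not pass at 2 weeks (-0.71). Of 25 mechanotransduction genes 1, 2 and 3 were higher and none lower (1, 4 and 6 adjusted over the list alone). The list had an adjusted p of 0.000378, 0.00709 and 0.00109 (0.0221, 0.134 and 0.0467 with an estimated correlation). Piezo1, a mechanically gated ion channel, rose at each week by 0.55 ± 0.12, 0.61 ± 0.12 and 0.65 ± 0.12 (adjusted p = 0.00604, 0.00169 and 0.000674). Piezo2 had -0.42 at 2 weeks and did not pass. Trpv4, a calcium channel that responds to cell swelling and load, rose by 0.88 ± 0.20 at 6 weeks (adjusted p = 0.00745, and 0.057 without rat 24). It passed at 4 weeks with the rat as a block (adjusted p = 0.0308 against 0.0636). Ctgf, a target of the YAP and TAZ regulators, had 0.72 at 4 and 0.79 at 6 weeks (adjusted p = 0.131 and 0.0699, or 0.0118 and 0.0104 with the rat as a block).

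Genes of the chondrocyte matrix mostly did not pass in cartilage. Of 19 measured, none was higher and 3 were lower at 2 weeks, 1 was higher at 4 weeks, and 1 was higher and 1 lower at 6 weeks. Adjusted over the list alone they were 0 and 4, 2 and 1, and 1 and 1. The list's adjusted p was 0.195, 0.11 and 0.979, and 0.0432 at 4 weeks with the rat as a block. Col2a1, the main collagen of cartilage, had log2 changes of 0.14 ± 0.33, 0.63 ± 0.34 and 0.76 ± 0.34 (adjusted p = 0.93, 0.495 and 0.353). It was higher in 8 of 8 rats at 6 weeks. Acan, the proteoglycan aggrecan, rose by 0.71 ± 0.19 at 4 and 0.73 ± 0.19 at 6 weeks (adjusted p = 0.0386 and 0.0289). These calls were kept in 4 and 1 of the 8 fits that left out 1 rat (0.141 without rat 14 and 0.165 without rat 24). Frzb, a secreted Wnt antagonist of cartilage, fell at 2 weeks (-0.93 ± 0.19, adjusted p = 0.00284) and 6 weeks (-0.87 ± 0.19, adjusted p = 0.00509). Prg4, the lubricating protein lubricin, did not pass (0.22 ± 0.32 at 2 weeks, adjusted p = 0.849).

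Lists of other cell types fell in cartilage by camera, but none of those calls held with an estimated correlation. The osteoblast and osteocyte list (10 genes, none passing) had medians of -0.78, -0.69 and -0.89 (adjusted p = 0.00257, 0.0264 and 0.000269, or 0.234, 0.519 and 0.162 with an estimated correlation). Its share of counts at 6 weeks was 0.349 ± 0.194% in sham and 0.150 ± 0.0465% in MMT knees, higher in 1 of 8 rats (exact sign-flip p = 0.0234). At 2 weeks the erythroid, lymphocyte, neutrophil and proliferation lists had adjusted p of 0.00257, 0.00181, 0.00431 and 0.00132 (0.61, 0.196, 0.626 and 0.62 with an estimated correlation). Their medians were -0.68, -1.0, -0.84 and -0.43, none of their genes passing. The proliferation median was 0.10 on the TPM scale without Mt-atp6. The neutrophil and proliferation lists also fell at 4 weeks (adjusted p = 0.0161 and 0.0415, or 0.767 and 0.826 with an estimated correlation). With the rat as a block so did the erythroid (0.0143, and 0.0475 at 6 weeks), lymphocyte (0.0115), skeletal muscle (0.00976) and endothelium lists (0.00527). The endothelium share in sham knees at 4 weeks was 0.0441 ± 0.0597% with 0.191% in the doubted library of rat 16, against 0.0201% in MMT knees. At 6 weeks the adipocyte, hypertrophy, endothelium, osteoclast and macrophage lists fell (adjusted p = 0.00212, 0.0017, 0.0017, 0.00566 and 0.0305, or 0.442, 0.337, 0.442, 0.442 and 0.574 with an estimated correlation). Their medians were -2.59, -0.49, -0.66, -1.53 and -0.45. The adipocyte share of sham cartilage at 6 weeks was 0.444% in rat 23 and 0.017 to 0.029% in the other rats, against a mean of 0.0199% in MMT knees, so the size of that fall rests largely on 1 library. The muscle list at 2 weeks had an adjusted p of 0.0196 (0.736 with an estimated correlation) and a median of 0.64. The mitochondrially encoded list had 0.00489 (0.519) and -0.29 at 4 weeks, and 0.0475 at 6 weeks with the rat as a block.

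The immediate early and heat shock list rose at 2 and 6 weeks (adjusted p = 0.00364 and 0.0305, or 0.234 and 0.442 with an estimated correlation), and at 4 weeks with the rat as a block (0.00976). Of its 14 genes 1, the AP-1 subunit Junb, was higher at each week (0.91 ± 0.19 at 2 weeks, adjusted p = 0.00392). The synovial fibroblast list rose at 2 and 4 weeks (adjusted p = 0.0272 and 0.0435, or 0.234 and 0.307 with an estimated correlation), and at 4 weeks not with the rat as a block (adjusted p = 0.103). The TGF-beta and BMP, Wnt, FoxO and autophagy, pain, and pericyte lists did not pass at any week (lowest adjusted p = 0.288, 0.584, 0.392, 0.22 and 0.173). The Schwann cell list had too few measured genes to test.

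The count in cartilage depended on the tool. DESeq2 called 295 genes at 2 weeks, and limma-voom 409 and 476 at 4 and 6 weeks. Fits of the 16 libraries alone called 1.19, 1.19 and 4.04% of the tested genes, against 1.75, 1.69 and 1.79% in the fit of all cartilage libraries. TPM values gave 31 genes at 2 weeks, all higher, and 25 at 4 weeks. On that scale the share of higher genes among those called went from 81.7 to 100.0% at 2 weeks and from 87.5 to 77.1% at 6 weeks. Leaving out 1 rat gave 1.06% at 2 weeks (rat 1), 1.02, 0.89 and 1% at 4 weeks (rats 9, 13 and 14), and 1.04, 1.05, 0.945, 1.16 and 0.977% at 6 weeks (rats 17, 19, 21, 22 and 24).

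In the menisci, of which the medial one was itself transected in the MMT knee, many genes of the extracellular matrix and its proteases were higher and many fat genes lower. As lists with an estimated correlation, the proteases passed at each week, the fibrous matrix at 2 and 4 weeks and the fat genes only at 6 weeks. Tnn (ENSRNOG00000002548) went from 8.88 ± 6.8 to 761.3 ± 338 CPM at 2 weeks. Its log2 changes were 6.34 ± 0.47, 5.32 ± 0.48 and 4.75 ± 0.44 (adjusted p = 8.04e-13, 6.13e-10 and 1.59e-09). Mmp13 went from 125.4 ± 52.1 to 329.9 ± 73.5 CPM at 2 weeks and rose by 1.39 ± 0.24, 2.18 ± 0.27 and 1.80 ± 0.26 (adjusted p = 8.35e-05, 2.92e-07 and 1.07e-05). Myoc fell at each week (-3.21 ± 0.28, -2.55 ± 0.28 and -2.12 ± 0.27, adjusted p = 1.01e-10, 3.24e-08 and 1.5e-06). Adipoq, the fat cell hormone adiponectin, averaged 571.8 CPM in sham and 89.2 CPM in MMT menisci at 6 weeks (-2.66 ± 0.41, adjusted p = 2.42e-05).

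**Figure D3:**
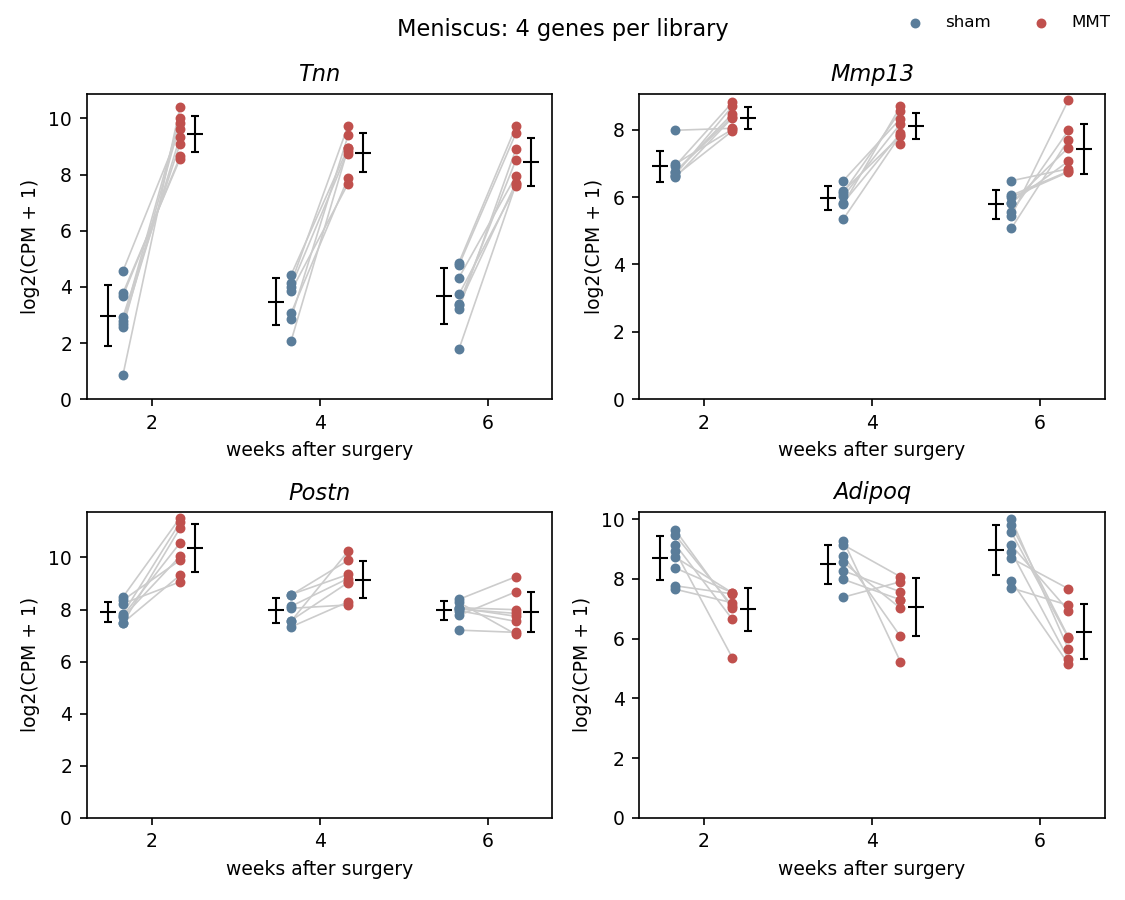
Each point is 1 meniscus library, as log2(CPM + 1) of Tnn, Mmp13, Postn and Adipoq against weeks after surgery. The colours, lines and marks are those of the cartilage plot, with n = 8, and 7 sham menisci at 4 weeks. Tnn rose at each week by 6.34, 5.32 and 4.75 on the log2 scale, and Postn by 2.65 at 2 weeks against 0.08, which did not pass, at 6 weeks.

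In meniscus 845 genes passed at 2 weeks (529 higher and 316 lower), 761 at 4 weeks (363 and 398) and 563 at 6 weeks (254 and 309), by edgeR over 10785 genes. Of the genes that rose, 150 did so at least 2-fold at 2 weeks and 81 at 6 weeks. Fbn2, a fibrillin of elastic microfibrils, rose by 5.09 ± 0.60, 4.93 ± 0.70 and 3.59 ± 0.63 (adjusted p = 4.09e-08, 3.84e-06 and 0.000177). C1qtnf3, a secreted protein of the C1q and TNF superfamily, rose by 4.61 ± 0.46, 4.46 ± 0.51 and 2.61 ± 0.47 (adjusted p = 1.11e-09, 5.01e-08 and 0.00022). Nefh and Stmn2, which encode a neurofilament subunit and a microtubule regulator of neurons, rose by 4.55 ± 0.64 and 3.23 ± 0.51 at 2 weeks (adjusted p = 2.46e-07 and 1.38e-05). Gsn, the actin-severing protein gelsolin, fell at each week (-2.24 ± 0.21, -1.91 ± 0.21 and -1.84 ± 0.21, adjusted p = 3.32e-10, 4.92e-08 and 3.09e-07). So did Grem1 (-1.95 ± 0.24, -2.02 ± 0.25 and -1.23 ± 0.23, adjusted p = 9.96e-08, 3.56e-07 and 0.00037). Cntfr fell at 4 and 6 weeks (-3.01 ± 0.48 and -2.71 ± 0.50, adjusted p = 7.51e-06 and 0.000172). Aqp7, a water and glycerol channel of fat cells, fell at 2 and 6 weeks (-2.62 ± 0.42 and -2.85 ± 0.43, adjusted p = 5.27e-06 and 6.52e-06).

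Of 22 fibrous matrix genes in meniscus 17, 13 and 13 were higher and none lower at 2, 4 and 6 weeks (21, 20 and 17 adjusted over the list alone). For the list the adjusted p was 2.04e-31, 5.41e-23 and 2.95e-15, and 0.00719, 0.0304 and 0.0901 with an estimated correlation. Col12a1, a collagen that binds along fibrils, rose by 2.86 ± 0.30, 2.48 ± 0.32 and 1.78 ± 0.30 (adjusted p = 4.82e-09, 4.62e-07 and 7.74e-05), and Lum, the proteoglycan lumican, rose by 1.98 ± 0.18, 1.73 ± 0.19 and 1.41 ± 0.18 (adjusted p = 1.42e-10, 2.75e-08 and 1.5e-06). Col1a1, the main collagen of fibrocartilage, rose by 0.95 ± 0.21, 1.44 ± 0.22 and 1.13 ± 0.21 (adjusted p = 0.00139, 1.17e-05 and 0.000292). Postn, the matricellular protein periostin, rose by 2.65 ± 0.34 at 2 weeks and 1.26 ± 0.34 at 4 weeks (adjusted p = 2.59e-07 and 0.0136, the latter 0.109 without rat 11). It had 0.08 ± 0.32 at 6 weeks (adjusted p = 0.944).

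Of 17 matrix protease genes 10, 11 and 8 were higher and none lower (11, 13 and 10 adjusted over the list alone). The list's adjusted p was 2.31e-14, 2.3e-14 and 5.69e-08, and 0.00116, 0.0012 and 0.0181 with an estimated correlation. Besides Mmp13, Mmp12, the macrophage elastase, rose by 3.70 ± 0.61, 5.27 ± 0.78 and 2.85 ± 0.69 (adjusted p = 1.84e-05, 3.99e-06 and 0.00626). Mmp3 rose by 1.99 ± 0.40, 1.87 ± 0.41 and 2.17 ± 0.40 (adjusted p = 0.000456, 0.00237 and 0.000292). Mmp14, a membrane-bound collagenase, and Mmp2, a gelatinase, rose by 1.97 ± 0.18 and 1.65 ± 0.17 at 2 weeks (adjusted p = 1.99e-10 and 3.15e-09). Adamts4, an aggrecanase, rose by 1.35 ± 0.25 at 2 and 1.03 ± 0.28 at 4 weeks (adjusted p = 9.11e-05 and 0.0109, the latter 0.0761 without rat 13). The protease inhibitor list did not pass (adjusted p = 0.47, 0.841 and 0.552). Of its 9 genes 3 were higher and 2 lower at 2 weeks, 2 and 3 at 4 weeks, and 2 and 1 at 6 weeks. Timp1 rose by 1.30 ± 0.16, 1.08 ± 0.17 and 1.31 ± 0.17.

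The osteoclast list rose at 4 and 6 weeks, with 1, 3 and 4 of 6 genes higher and none lower (1, 3 and 5 adjusted over the list alone). Its adjusted p was 0.0813, 2.51e-05 and 1.2e-06, and 0.0304 and 0.0181 at 4 and 6 weeks with an estimated correlation. Ctsk, the bone-resorbing protease cathepsin K, rose by 1.33 ± 0.19 at 4 weeks (adjusted p = 3.29e-06). Acp5, the tartrate-resistant acid phosphatase, and Atp6v0d2, a proton pump subunit, rose by 1.18 ± 0.22 and 1.91 ± 0.38 at 6 weeks (adjusted p = 0.000292 and 0.000392). Mmp9, a gelatinase, rose by 1.27 ± 0.30 at 4 and 0.93 ± 0.29 at 6 weeks (adjusted p = 0.00418 and 0.049, the latter 0.26 without rat 23 and 0.15 with the rat as a block). The proliferation list rose at 4 and 6 weeks (adjusted p = 2.61e-07 and 3.5e-10, or 0.221 and 0.179 with an estimated correlation). It also fell at 2 weeks with the rat as a block (0.0272). Of its 20 genes 0, 0 and 3 were higher, and 18 adjusted over the list alone at 6 weeks. The mitotic kinase Cdk1 rose by 1.04 ± 0.26 at 6 weeks (adjusted p = 0.00873). The erythroid list fell at 2 weeks and rose at 4 and 6 weeks (medians -0.43, 0.57 and 0.83, adjusted p = 0.0194, 0.00022 and 1.2e-06, or 0.724, 0.366 and 0.244 with an estimated correlation). Its share of counts at 6 weeks was 1.71 ± 0.432% in sham and 2.71 ± 1.24% in MMT menisci, higher in 6 of 8 rats (exact sign-flip p = 0.0469).

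The adipocyte list fell in meniscus, with 10, 8 and 14 of 15 genes lower and none higher at 2, 4 and 6 weeks (14, 13 and 15 adjusted over the list alone). The medians were -1.32, -1.19 and -2.38. Its adjusted p was 1.38e-09, 1.05e-09 and 6.87e-24, and 0.227, 0.137 and 0.0181 with an estimated correlation. Cidec, a lipid droplet protein, and Pck1, an enzyme of glucose and glycerol synthesis, fell at 6 weeks (-2.80 ± 0.48 and -2.83 ± 0.44, adjusted p = 0.000126 and 2.92e-05). At 2 weeks Fabp4, a fatty acid carrier, and Adipoq fell (-1.28 ± 0.29 and -1.76 ± 0.39, adjusted p = 0.00249 and 0.0017), Fabp4 not with the rat as a block (adjusted p = 0.0724). At 4 weeks Adipoq had -1.32 ± 0.40 (adjusted p = 0.031, or 0.151 with the rat as a block and 0.163 without rat 15). The share of counts in adipocyte genes was 0.471 ± 0.219% in sham and 0.108 ± 0.0421% in MMT menisci at 6 weeks, lower in 8 of 8 rats (exact sign-flip p = 0.00781, the smallest possible; 0.176 adjusted over 90 tests).

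Some genes of the chondrocyte matrix were lower in meniscus at 2 and 4 weeks, but the list call did not hold with an estimated correlation. Of 18 genes 1 was higher and 8 lower at 2 weeks, 1 and 5 at 4 weeks, and 3 and 3 at 6 weeks (2 and 9, 3 and 7, and 5 and 3 adjusted over the list alone). The list's adjusted p was 3.99e-07, 0.000226 and 0.422, and 0.213 and 0.221 at 2 and 4 weeks with an estimated correlation. Cytl1, a cytokine-like protein of chondrocytes, fell at each week (-1.97 ± 0.26, -2.38 ± 0.27 and -1.52 ± 0.26, adjusted p = 4.82e-07, 5.01e-08 and 8.99e-05). Chad, the matrix protein chondroadherin, fell at each week (-1.31 ± 0.20, -1.47 ± 0.20 and -0.76 ± 0.19, adjusted p = 5.21e-06, 1.77e-06 and 0.0114). At 6 weeks Col2a1 rose by 1.32 ± 0.23 (adjusted p = 0.000172, 8 of 8 rats, from 1014 to 2535 CPM). Col9a1, a collagen of cartilage fibrils, rose by 2.68 ± 0.49 (adjusted p = 0.000286). Acan rose by 0.67 ± 0.19 at 2 weeks (adjusted p = 0.0161, and 0.124 without rat 6). It had 0.57 ± 0.20 and 0.60 ± 0.19 later (adjusted p = 0.0656 and 0.0504). The hypertrophy list did not pass (lowest adjusted p = 0.053 at 6 weeks, or 0.0264, higher, with the rat as a block). Its members Mmp13 and Spp1, the bone protein osteopontin, rose, the latter by 0.99 at 6 weeks. Col10a1, the collagen of hypertrophic cartilage, fell at 4 weeks (-1.46 ± 0.42, adjusted p = 0.0224, or 0.0613 with the rat as a block and 0.102 without rat 13).

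Of 13 endothelium genes in meniscus 1, 6 and 2 were lower and none higher at 2, 4 and 6 weeks (2, 8 and 3 adjusted over the list alone). As a list they had an adjusted p of 0.41, 9.71e-09 and 0.00267 (0.0865 and 0.433 at 4 and 6 weeks with an estimated correlation). Ramp2, a receptor partner for adrenomedullin, fell at each week (-0.54 ± 0.11, -0.88 ± 0.11 and -0.71 ± 0.11, adjusted p = 0.000304, 6.67e-08 and 1.06e-05). Tek, the angiopoietin receptor, fell at 4 weeks (-0.68 ± 0.16, adjusted p = 0.00227). The endothelium share of counts at 4 weeks was 0.191 ± 0.0273% in sham and 0.124 ± 0.0200% in MMT menisci, lower in 7 of 7 rats (exact sign-flip p = 0.0156). The pericyte and Schwann cell lists fell at 4 weeks (adjusted p = 0.00106 and 0.000744, or 0.221 and 0.0711 with an estimated correlation). Acta2, smooth muscle actin, had -0.97 ± 0.27 (adjusted p = 0.0165, and 0.0712 without rat 10). The pain list passed at 4 weeks (adjusted p = 0.0459, or 0.109 with an estimated correlation), and with the rat as a block fell at 6 weeks (0.0347). Ngfr, the low-affinity neurotrophin receptor, fell at 4 weeks (-1.75 ± 0.38, adjusted p = 0.000921).

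The Wnt list rose in meniscus at 4 and 6 weeks (adjusted p = 0.0678, 0.00125 and 0.0205, or 0.0865 and 0.227 at 4 and 6 weeks with an estimated correlation). Of its 18 genes 5, 7 and 4 were higher and 1, 2 and 0 lower. Sfrp4, a secreted Wnt regulator, rose by 1.48 ± 0.22 at 2 and 1.71 ± 0.23 at 4 weeks. The mechanotransduction list rose at 2 weeks (adjusted p = 0.0194, 0.789 and 0.403, or 0.226 at 2 weeks with an estimated correlation). Of its 26 genes 4, 2 and 1 were higher. Piezo2 rose by 1.30 ± 0.32 at 2 and 1.24 ± 0.33 at 4 weeks (adjusted p = 0.00558 and 0.0116, the latter 0.0889 with the rat as a block and 0.0979 without rat 11). Piezo1 had 0.29 ± 0.10 (adjusted p = 0.0636). The osteoblast list fell at 2 weeks (adjusted p = 0.0194, or 0.54 with an estimated correlation), and with the rat as a block rose at 6 weeks (0.0161). The neutrophil list rose at 4 weeks (adjusted p = 0.000379, or 0.366 with an estimated correlation). Of the lists that did not pass at any week, the inflammatory (0.0012, higher, at 6 weeks), lymphocyte (0.0155, lower, at 2 weeks) and mitochondrially encoded lists (0.0237, higher, at 2 weeks) passed with the rat as a block. The others were TGF-beta and BMP, FoxO and autophagy, immediate early, macrophage, skeletal muscle and synovial fibroblast (lowest adjusted p = 0.51, 0.422, 0.453, 0.422, 0.571 and 0.587). Ccl2 (0.66 ± 0.39, adjusted p = 0.375) and Inhba (0.49 ± 0.16, adjusted p = 0.0542, or 0.0267 with the rat as a block) did not pass at 2 weeks. At 6 weeks Inhba was higher (0.715 ± 0.157, adjusted p = 0.00211, 8 of 8 rats).

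On the unscaled TPM values, where Mt-atp6 takes most of the total in some libraries, the median of all genes in meniscus moved by -0.232 at 2 weeks and -0.849 at 6 weeks against the counts, and by 0.009 and -0.002 without Mt-atp6. On that scale 34, 21 and 7461 genes passed (12 higher and 22 lower, 9 and 12, and 22 and 7439). Without Mt-atp6 they were 510 at 2 weeks (307 and 203), 567 at 4 weeks (146 and 421) and 328 at 6 weeks (195 of them lower). At 6 weeks on the unscaled values the medians of the fibrous matrix, matrix protease, osteoclast, proliferation, erythroid and Wnt lists were negative, and above 0 relative to the shift. Leaving out 1 rat gave 495 genes at 4 weeks (rat 15) and 368, 366, 361 and 365 at 6 weeks (rats 18, 20, 21 and 23).

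**Figure D4:**
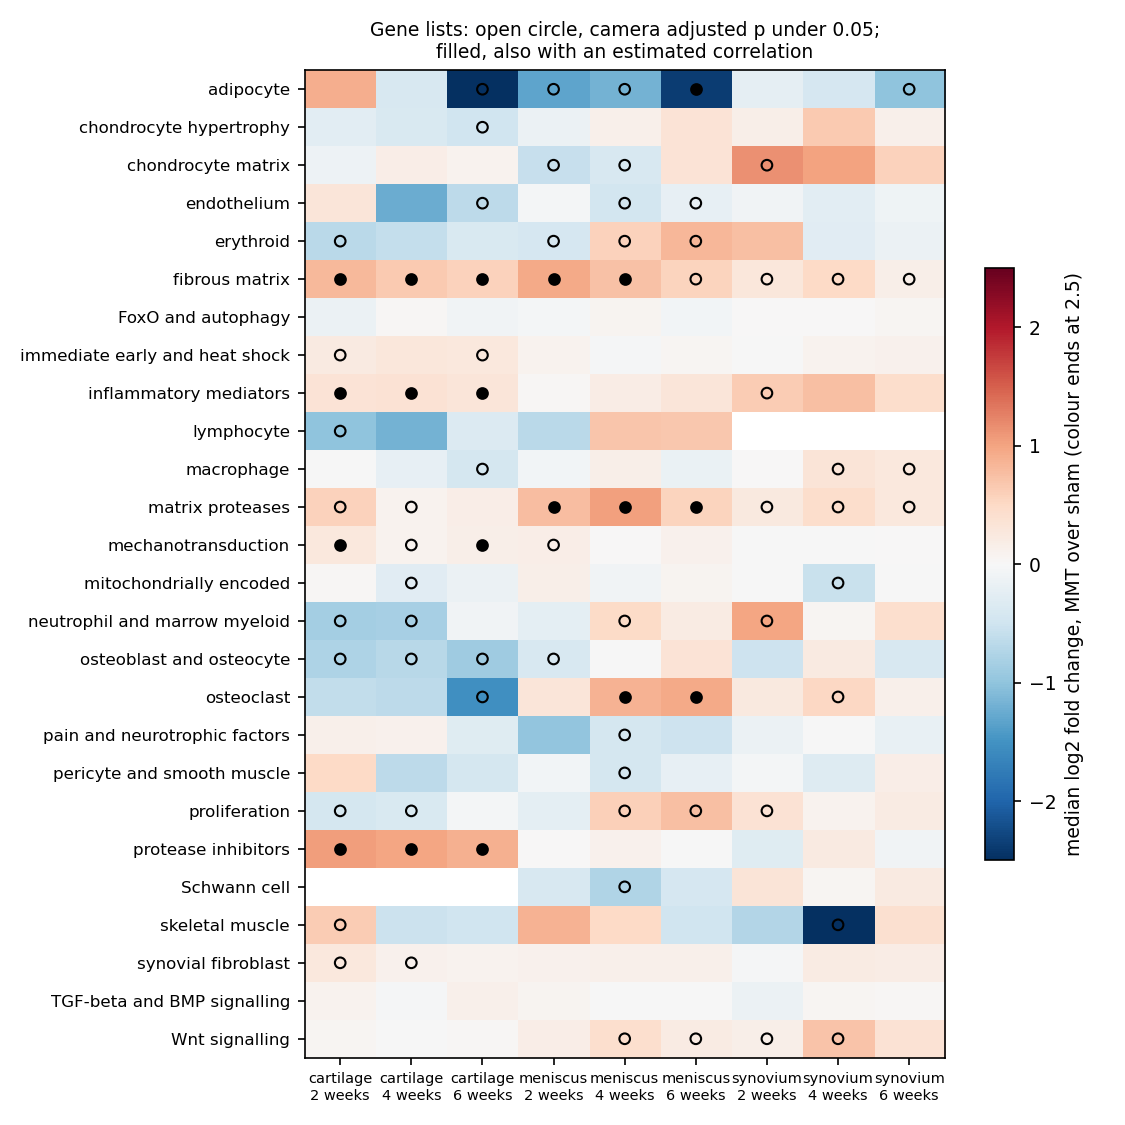
Each cell of the heat map is the median log2 fold change, MMT over sham, of 1 of the 26 gene lists (vertical axis) in 1 tissue and week (horizontal axis). Colour ends at 2.5, and white marks lists not tested. Open circles mark a camera adjusted p under 0.05, and filled circles a list that also passed with an estimated correlation, as the fibrous matrix and matrix protease lists did in meniscus at 2 and 4 weeks.

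In synovium, few genes differed between knees at 2 and 6 weeks. Most of those called at 4 weeks were lower, with a median log2 difference of -3.69 in rats 9 and 10 and -0.29 in the other 6 rats. Megf6, a secreted protein with epidermal growth factor repeats, passed alone at 2 weeks (from 2.52 ± 4.15 to 23.5 ± 11.4 CPM, log2 change 3.07 ± 0.57, adjusted p = 0.0203, 8 of 8 rats). At 4 weeks Mmp13 rose by 4.28 ± 1.15 (adjusted p = 0.0386, 8 of 8 rats), Acan by 4.53 ± 1.17 (adjusted p = 0.0323) and Sfrp4 by 1.67 ± 0.36 (adjusted p = 0.0201, 8 of 8 rats). Myh7, the myosin heavy chain of slow muscle, averaged 1456 ± 2680 CPM in sham and 1.22 ± 1.47 CPM in MMT synovium at 4 weeks (-10.26 ± 2.62, adjusted p = 0.0323). It was lower in only 5 of 8 rats and higher in 1. Without rat 9 or without rat 10 no gene passed at 4 weeks. The 33 genes called higher at 4 weeks had medians of 0.845 and 0.883 in those rats and 0.717 to 1.52 in the others.

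In synovium 1 gene passed at 2 weeks, 244 at 4 weeks (33 higher and 211 lower) and 0 at 6 weeks, by edgeR over 10551 genes. At an unadjusted p under 0.05 there were 492, 1363 and 458 genes, and at 6 weeks DESeq2 called 2 and limma-voom none. At 4 weeks Lox, which crosslinks collagen, rose by 1.34 ± 0.34 (adjusted p = 0.0323, 8 of 8 rats), Megf6 by 2.85 ± 0.60 (adjusted p = 0.0201, 7 of 8 rats) and Spp1 by 2.59 ± 0.71 (adjusted p = 0.0417). Sectm1a, a secreted and membrane protein, and Acp5 rose by 2.38 ± 0.67 and 0.82 ± 0.23 (adjusted p = 0.0457 and 0.0417). Des, the muscle filament desmin, fell in 8 of 8 rats (-2.38 ± 0.54, adjusted p = 0.0258). Lower too were the sarcomere genes Ldb3 (-3.94 ± 0.85, adjusted p = 0.0201), Xirp1 (-4.25 ± 0.88, adjusted p = 0.0201) and Tmod4 (-4.86 ± 1.23, adjusted p = 0.0323). Tnnt1 and Tnnt3, the troponins T of slow and fast muscle, had -8.04 ± 2.13 and -3.79 ± 1.01 (adjusted p = 0.0364 and 0.0385), and Atp2a1, the calcium pump of fast muscle, -5.68 ± 1.46 (adjusted p = 0.0323). The transcription factor Mef2c, the fatty acid carrier Fabp3 and the stretch-induced Ankrd1 had -1.37 ± 0.37, -4.05 ± 1.02 and -3.99 ± 1.02 (adjusted p = 0.0411, 0.0315 and 0.0323). With the rat as a block Megf6 and Lox kept an adjusted p under 0.05, and Mmp14 gained one (0.0297). With it Sfrp4, Acp5, Mmp13, Acan, Spp1, Sectm1a, Des and Myh7 did not pass (0.0879, 0.0626, 0.165, 0.232, 0.581, 0.226, 0.256 and 0.166). The log2 changes with the block were close to those without it for Sfrp4 (1.665), Acp5 (0.858), Mmp13 (4.067) and Acan (4.137), and smaller for Spp1 (1.366) and Des (-1.3). Nor did Ldb3, Xirp1, Tmod4, Tnnt1, Tnnt3, Atp2a1, Mef2c, Fabp3 and Ankrd1 (0.313, 0.107, 0.202, 0.262, 0.716, 0.591, 0.46, 0.269 and 0.183), and Tnnt3 was -0.774 with the block. At 6 weeks Sfrp4 had 1.62 ± 0.36, higher in 8 of 8 rats (adjusted p = 0.33), Timp1 1.06 ± 0.29 (0.65) and Mmp13 2.02 ± 0.94 (1).

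**Figure D5:**
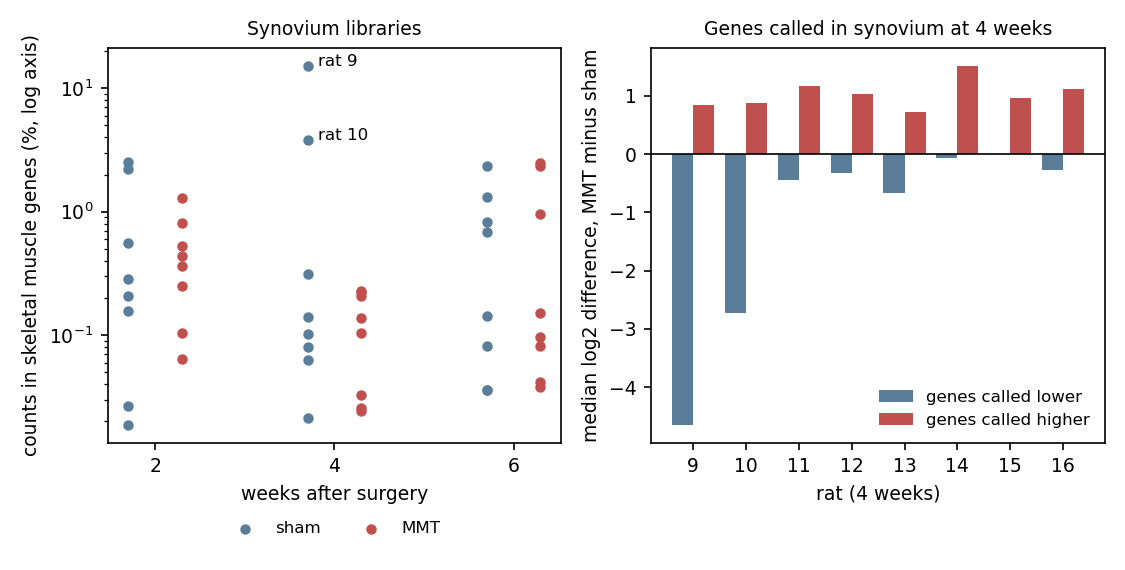
The left panel gives the share of counts in skeletal muscle genes (percent, log axis) of each synovium library by week, sham in blue and MMT in red. The right panel gives, for each rat at 4 weeks, the median log2 difference (MMT minus sham) of the genes called lower (blue) and higher (red). Rats 9 and 10 had sham muscle shares of 15.2% and 3.79% and medians of -4.65 and -2.72 for the genes called lower.

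Of 14 skeletal muscle genes in synovium, 9 were lower at 4 weeks and 14 adjusted over the list alone. The list's median was -4.97 and its adjusted p 0.0053 (0.746 with an estimated correlation). The muscle share of counts at 4 weeks was 2.47 ± 5.32% in sham and 0.123 ± 0.0894% in MMT synovium (exact sign-flip p = 0.18). It reached 15.2% in the sham library of rat 9 (Wilson 95% interval 15.2 to 15.3%) and 3.79% in that of rat 10 (3.76 to 3.81%). With the mean of the muscle list as a covariate 5 genes passed at 4 weeks (4 higher and 1 lower).

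The fibrous matrix list rose in synovium at each week by camera (adjusted p = 6.82e-05, 1.8e-07 and 0.000383, or 0.593, 0.583 and 0.808 with an estimated correlation). Its medians were 0.28, 0.49 and 0.15. On unscaled TPM values the last was -0.41, where the median of all genes moved by -0.560, and 0.148 relative to that shift. Of 22 genes 0, 1 and 0 passed (3, 2 and 0 adjusted over the list alone). The matrix protease list rose likewise (adjusted p = 0.0174, 7.04e-05 and 0.00928, or 0.527, 0.159 and 0.729 with an estimated correlation). Its median at 6 weeks was -0.27 on unscaled TPM values and 0.287 relative to the shift, and Mmp13 was the 1 of 17 genes to pass, at 4 weeks. The Wnt list rose at 2 and 4 weeks (adjusted p = 0.0112 and 4.52e-06, or 0.422 and 0.12 with an estimated correlation), and at 6 weeks with the rat as a block (0.00738). Adjusted over the list alone, 2, 7 and 2 of 14 genes were higher. The chondrocyte matrix list rose at 2 weeks (median 1.15, adjusted p = 0.0067, or 0.422 with an estimated correlation), and at 4 weeks with the rat as a block (0.00336). Its share of counts at 2 weeks was higher in 7 of 8 rats (0.0629% against 0.0874%, exact sign-flip p = 0.0312). The macrophage list rose at 4 and 6 weeks (adjusted p = 0.00451 and 0.00591, or 0.746 and 0.808 with an estimated correlation). Its median at 6 weeks was -0.40 on unscaled TPM values and 0.162 relative to the shift. The osteoclast list rose at 4 weeks (adjusted p = 0.00866, or 0.159). The inflammatory, neutrophil and proliferation lists rose at 2 weeks (adjusted p = 0.0174, 0.0116 and 0.018, or 0.422, 0.527 and 0.527 with an estimated correlation), none of their genes passing. The proliferation median was -0.12 over the 2 genes left on unscaled TPM values, or -0.051 relative to all genes. The inflammatory list also rose at 4 and 6 weeks with the rat as a block (0.0068 and 0.0209).

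The adipocyte list fell in synovium at 6 weeks (median -1.0, adjusted p = 1.39e-10, or 0.722 with an estimated correlation), none of its 16 genes passing. It also fell at 4 weeks with the rat as a block (0.000136). Its share of counts at 6 weeks was 1.08 ± 0.840% in sham and 0.559 ± 0.468% in MMT synovium, higher in 1 of 8 rats (exact sign-flip p = 0.0156). The mitochondrially encoded list fell at 4 weeks (median -0.55, adjusted p = 0.0041, or 0.656 with an estimated correlation), and its median on unscaled TPM values was 0.34, or -0.208 relative to all genes. With the rat as a block the endothelium list (0.0129, lower, at 4 weeks), the erythroid list (0.000502, higher, at 2 weeks), the osteoblast list (0.0216, lower, at 6 weeks) and the synovial fibroblast list (0.0444, higher, at 6 weeks) passed, which they did not otherwise. The remaining lists (FoxO and autophagy, Schwann cell, TGF-beta and BMP, hypertrophy, immediate early, mechanotransduction, pain, pericyte and protease inhibitors) did not pass (lowest adjusted p = 0.784, 0.177, 0.257, 0.115, 0.615, 0.739, 0.203, 0.203 and 0.491). The lymphocyte list had too few measured genes to test. Over all tissues and weeks 80 of 228 list tests passed by camera and 19 of those with an estimated correlation. Where a list's median, mean and test differed in sign, in 33 of the 228, none had passed.

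The synovium counts were not stable to the choice of test. At 2 weeks Megf6 passed in 2 of 8 fits that left out 1 rat (0.216 without rat 3). No gene passed without rats 2, 3, 4, 6, 7 or 8, and 6 did without rat 5. At 4 weeks limma-voom, the plate prefix as a covariate and TPM values gave 0 genes, the rat as a block 10 (6 higher and 4 lower), fits of the 16 libraries alone 3 and no filter 75. Leaving out rats 6 and 11 gave 1.21% of the tested genes against 2.31%, and leaving out the low-depth library of rat 16 alone 313 genes. Leaving out the sham library of rat 9, with the highest muscle share, gave 0. The genes called higher had a median of 1.3 without it, 1.14 with the plate covariate and 1.23 with the block, against 1.26. The lower ones had -1.24, -1.3 and -1.33, against -2.27. The genes were picked in these libraries, so a kept median decides nothing. The median of all genes on unscaled TPM values moved by 0.549 at 4 weeks and -0.560 at 6 weeks (0.169 and 0.067 without Mt-atp6).

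Whether the effect of MMT differed among the 3 times was tested within each tissue. In meniscus 9 genes differed by edgeR (998 at an unadjusted p under 0.05). Postn and Pdgfrb, the receptor for platelet-derived growth factor on mural cells and fibroblasts, had an adjusted p of 0.0246, as did Eps8l2, an actin regulator, and the tubulin Tubb2b. Postn went from 2.65 to 0.08 between 2 and 6 weeks. Col2a1 (-0.34 ± 0.23 at 2 weeks and 1.32 ± 0.23 at 6 weeks), the actin-binding Lima1 and the peptidase Dpp4 had 0.0434, and the growth factor Mdk 0.0276. With the rat as a block Col2a1 had 0.0555 and Dpp4 0.0506. In cartilage and synovium no gene differed by edgeR (241 and 490 at an unadjusted p under 0.05). Nor did any by DESeq2 or limma-voom in cartilage, while DESeq2 called 1 in synovium and limma-voom none. The log2 change of Il11 in cartilage, 6.32 at 2 weeks and 3.68 at 6 weeks, was thus not shown to differ with time. In meniscus the count was 34 with DESeq2, 5 with the plate prefix as a covariate, 2 without rats 6 and 11, 46 on TPM values and 0 on TPM values without Mt-atp6.

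Many genes passed at more than 1 time, in different rats. In cartilage 71 genes were higher and 3 lower at all 3 times. Of the genes called at any time, 27.3% of the higher and 4.55% of the lower ones in cartilage were called at all 3, and 13.8% and 15.1% in meniscus. Between 2 and 4 weeks 83 genes rose at both times in cartilage, against 2.1 that chance overlap would give, and 224 in meniscus, against 17.81. Across genes, which are not independent replicates, the log2 changes had Pearson correlations between 2 and 4, 2 and 6, and 4 and 6 weeks of 0.45, 0.401 and 0.598 in cartilage. They were 0.556, 0.449 and 0.596 in meniscus and 0.437, 0.291 and 0.147 in synovium. In both tissues and at all 3 times 19 genes were higher and 1, Cntfr, lower. The 19 included Timp1, Tnfaip6, Col5a1, Col6a3, Htra1 and Sod2. Gja1, the gap junction protein connexin 43, had 1.53, 1.24 and 1.09 in cartilage and 1.21, 1.43 and 1.05 in meniscus. Chi3l1, a secreted glycoprotein of chondrocytes and macrophages, had 2.08, 2.08 and 2.30 in cartilage and 1.66, 1.43 and 1.86 in meniscus. Both were chosen after their values were seen.

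Whether MMT acted differently in the 3 tissues was tested on the effect averaged over times. Il11 and Ccl2 rose more in cartilage than in meniscus, while Fbn2 and Mmp13 rose more in meniscus. Il11 had a mean log2 change of 4.94 ± 0.28 in cartilage, 1.04 ± 0.40 in meniscus and 0.25 ± 0.43 in synovium (difference of meniscus and cartilage -3.90 ± 0.54, adjusted p = 2.6e-08). Fbn2 had -0.07 in cartilage and 4.57 in meniscus (difference 4.64 ± 0.99, adjusted p = 0.000626). Col2a1 had a mean log2 change of 5.54 ± 0.66 in synovium, from 1.5 ± 2.65 CPM in sham to 74.6 ± 217 CPM in MMT knees, where the SD exceeds the mean. Other cartilage genes moved with it, as Chad went from 5.46 to 26.62 CPM and Clec3a from 1.15 to 13.33 CPM. Cartilage carried into the MMT synovium was not tested and stays open.

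Between meniscus and cartilage 494 genes differed in effect by edgeR (171 more positive in meniscus and 323 in cartilage). The differences were -2.79 ± 0.44 for Ccl2, -1.65 ± 0.22 for Inhba and -1.04 ± 0.27 for Col3a1 (adjusted p = 1.16e-06, 2.21e-08 and 0.00985), and 2.25 ± 0.45 for Mmp13 (adjusted p = 0.000224). The channels Piezo1 and Piezo2 differed in opposite directions (-0.53 ± 0.11 and 1.42 ± 0.28, adjusted p = 0.000284 and 0.000174), and Ctgf had -0.86 ± 0.19 (adjusted p = 0.00138). Lamb3, a laminin chain of basement membranes, had 1.54 in cartilage and -1.30 in meniscus (difference -2.84 ± 0.34, adjusted p = 1.49e-10). The keratin Krt13 had 2.11 and -0.90 (-3.01 ± 0.45, adjusted p = 2.94e-07). The chemokine Ccl9, the calcium channel subunit Cacnb3 and the fibroblast membrane protein Lrrc15 differed by 2.78 ± 0.53, 2.83 ± 0.53 and 2.68 ± 0.69 (adjusted p = 8.25e-05, 7.24e-05 and 0.00869).

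Between synovium and cartilage 796 genes differed in effect (279 more positive in synovium and 517 in cartilage). Col2a1 differed by 5.02 ± 0.80, Clec3a, a lectin of cartilage, by 4.18 ± 0.68, Chad by 2.73 ± 0.47, Acan by 2.19 ± 0.44 and Mmp13 by 3.25 ± 0.66 (adjusted p = 1.81e-06, 2.77e-06, 1.28e-05, 0.00027 and 0.000336). Il11, Ccl2, Inhba, Col3a1, Tnc and Piezo1 had -4.69 ± 0.63, -2.5 ± 0.44, -1.64 ± 0.23, -1.52 ± 0.27, -1.35 ± 0.30 and -0.68 ± 0.11 (adjusted p = 1.7e-08, 1.8e-05, 4.35e-08, 2.42e-05, 0.00115 and 1.58e-06). Il1b and Piezo2 had 1.41 ± 0.46 and 0.88 ± 0.29 (adjusted p = 0.0421 and 0.0441). The muscle genes Sln, Myh7 and Tnni1 had -5.16 ± 1.57, -3.99 ± 1.18 and -3.93 ± 1.05 (adjusted p = 0.0288, 0.0233 and 0.0106), with the muscle transcripts of the sham synovium of rats 9 and 10 among the values. Between synovium and meniscus 68 genes were more positive in synovium and 76 in meniscus. Clec3a, Col2a1, Chad, Acan and Mfi2, the iron-binding melanotransferrin, differed by 5.18 ± 0.67, 5.16 ± 0.80, 3.41 ± 0.47, 2.24 ± 0.44 and 2.73 ± 0.66 (adjusted p = 3.35e-08, 4.96e-06, 3.1e-07, 0.00084 and 0.0134). C1qtnf3 and Fbn2 had -2.91 ± 0.47 and -3.20 ± 0.59 (adjusted p = 1.28e-05 and 0.000237). The muscle genes Tnnt1 and Rpl3l had -3.85 ± 1.07 and -2.68 ± 0.70 (adjusted p = 0.0432 and 0.0268, or 0.0961 and 0.0752 with the rat as a block). DESeq2 gave 224 genes for synovium and meniscus and limma-voom 855 for meniscus and cartilage (362 and 493).

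Sham knees served to compare the tissues themselves. Cartilage genes set cartilage apart, with Col2a1 at 25890 ± 19400 CPM in sham cartilage, 1598 ± 757 CPM in sham meniscus and 1.5 ± 2.65 CPM in sham synovium. Chad averaged 20660, 2593 and 5.46 CPM and Clec3a 10380, 940.3 and 1.15 CPM. The number of genes that differed was 6605 between meniscus and cartilage (3348 higher in meniscus and 3257 lower), 7652 between synovium and cartilage (3898 and 3754) and 4116 between synovium and meniscus (2229 and 1887), by edgeR over 11788 genes.

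Higher in sham meniscus than in sham cartilage were Actg2, the smooth muscle gamma actin (6.48 ± 0.59, adjusted p = 2.24e-18), Crabp1, a retinoic acid carrier (5.85 ± 0.47, adjusted p = 4.6e-22), and Col28a1, a collagen of peripheral nerve (5.67 ± 0.41, adjusted p = 2.47e-25). Lower were Col9a1 (-4.95 ± 0.30, adjusted p = 1.43e-30) and the transcription factor Nkx6-1 (-5.01 ± 0.36, adjusted p = 3.32e-24). In synovium against cartilage, Actg2 had 6.81 ± 0.58 (adjusted p = 2.44e-20). Col2a1 and Chad had -13.93 ± 0.79 and -11.92 ± 0.47 (adjusted p = 4.17e-34 and 1.65e-48). In synovium against meniscus, Col2a1 had -10.00 ± 0.71 (adjusted p = 5.14e-25). The muscle genes Myh7 and Tnni1 had 6.04 ± 0.85 and 5.78 ± 0.75 (adjusted p = 1.95e-09 and 7.42e-11). Myh7 averaged 694.6 ± 1630 CPM in sham synovium, a mean that rests on few libraries.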

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

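The tests of explanations and the counts of other splits in this part were chosen after the results were seen, and the tests of differences between times and tissues were planned.

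The effect of MMT differed between tissues or times for 21 values of the core genes. Between meniscus and cartilage 494 genes differed (4.19% of those tested), among them Col3a1 (-1.04), Mmp13 (2.25), Piezo1 (-0.53), Piezo2 (1.42), Ctgf (-0.86), Ccl2 (-2.79) and Inhba (-1.65). Between synovium and cartilage 796 genes differed (6.75%), among them Col2a1 (5.02), Acan (2.19), Col3a1 (-1.52), Tnc (-1.35), Mmp13 (3.25), Piezo1 (-0.68), Piezo2 (0.88), Ccl2 (-2.5), Il1b (1.41) and Inhba (-1.64). Between synovium and meniscus 1.22% of the tested genes differed, among them Col2a1 (5.16) and Acan (2.24). Among the 3 times 9 genes (0.0834%) differed in meniscus, among them Col2a1 (adjusted p = 0.0434) and Postn (adjusted p = 0.0246).

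The genes lower in synovium after MMT at 4 weeks (211) may come from skeletal muscle in the sham libraries of rats 9 and 10. Their median log2 difference was -3.69 in those 2 rats and -0.29 in the other 6. Myh7 averaged 1456 ± 2680 CPM over the 8 sham libraries of that week, and the fit held all 14 muscle list genes. A plate difference stays open, as with the prefix as a covariate 0 of the 211 passed. The 3 other prefix 3 libraries (sham only for rat 11) had a median muscle share of 0.104% (0.102 to 0.223%). The 11 of prefix 4 had 0.0212 to 0.312%. With the muscle list as a covariate 1 of the 211 passed. Their median went from -2.27 (quartiles -4.82 and -0.949) to -0.642 (-1.07 and -0.449). Of the 33 genes called higher 3 passed (median 1.28 against 1.26). Whether MMT also lowers the 211 genes stays open, as the covariate is made of muscle genes.

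The sham cartilage library of rat 16 at 4 weeks correlated better with sham meniscus than with sham cartilage. Meniscus tissue alone is argued against, since 87 genes over 8-fold higher in sham cartilage stood 17.6% of the way from the sham meniscus to the sham cartilage mean, outside the range of the 23 sham menisci (-4.06 to 3.21%) and below the 23 other sham cartilage libraries (at least 33.8%). An exchange with another analysed library is argued against too, since 0 other libraries correlated best with another tissue. A mixture of both tissues is a candidate explanation, with 257 meniscus genes at 1.032 on a log2 scale from sham cartilage (0) to sham meniscus (1). No biological explanation was tested, and an exchange of material with the sham meniscus of rat 16, not analysed here, stays open.

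The genes higher in cartilage after MMT could come from more meniscus or synovium carried into the MMT samples. Against meniscus, 100 abundant meniscus genes gave a mean share over rats of at most 4.45 ± 7.62% over the 3 times. The rise would need 64.3 to 76.9%, as a median over the genes called higher. Against synovium, the share was at most 2.46%, where 74.5 to 94.7% would be needed. The side of the body and the surgery cannot be told apart, since 0 rats had MMT on the left knee. A response of cartilage to MMT stays open with it.

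For the number of genes per comparison, other splits of the same libraries were counted, the real split included. Chance can be excluded in cartilage at 4 and 6 weeks (1 of 100 each, 174 genes against at most 1 and 184 against 0). At 2 weeks (2 of 100, 180 against 195) it is not excluded, since an exchange within rats gave more. The split with 195 genes exchanged knees within rats, kept 10 of 16 libraries as in the real split and followed neither plate, depth nor muscle share. Chance can be excluded in meniscus at each week (1 of 100 each, 845 against 358, 761 against 16 and 563 against 51). Its time difference (1 of 40, 9 against 1) stays open, as alternatives gave 0 to 46 genes. In synovium at 2 weeks (1 of 100, 1 against 0) the count is 1 gene, lost in 6 of 8 fits without 1 rat, so the splits carry little weight. At 4 weeks 2 of 100 splits gave as many (244 against 478), and those that exchanged knees within rats gave at most 221. No gene passed without rat 9 or without rat 10, so chance is not excluded there either. What gave the split with 478 genes its count was not found, as its muscle gap (0.862) was close to the median (0.904). No gene was called in synovium at 6 weeks (100 of 100, 0 against 2) or for the time differences of cartilage and synovium (40 of 40 each, 0 against 0), so the splits test nothing there. For differences between tissues in the effect, 1 of 21 splits, the lowest possible share, gave as many genes (494 against 50, 796 against 213, and 68 higher and 76 lower against 2), so chance can be excluded by this count. In sham knees the counts were 6605 against 455, 7652 against 539 and 4116 against 1135. There the other splits mixed unlike tissues and could hardly give as many, so they decide nothing.

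Each of the 18 groups was tested on 6 measures for a library far from the other 7 or 6, and 11 tests met the criterion, where chance gives about 1 in 20. The sham cartilage of rat 6 at 2 weeks had 280627 counts and 9082 genes detected. The chondrocyte matrix share was 2.4% in the sham cartilage of rat 2 at 2 weeks (Wilson 95% interval 2.38 to 2.42%, others 6.2 to 9.88%) and 2.59% in the MMT cartilage of rat 6 at 2 weeks (2.56 to 2.61%, others 5.13 to 8.68%). The muscle share was 1.51% in the MMT meniscus of rat 5 at 2 weeks (1.49 to 1.53%). The MMT synovium of rat 7 at 2 weeks had 1065105 counts. The sham cartilage of rat 16 at 4 weeks had an adipocyte share of 0.532% (0.517 to 0.547%) and a chondrocyte matrix share of 2.05% (2.02 to 2.08%). The sham synovium of rat 16 at 4 weeks had 9956 genes detected. The adipocyte share was 0.444% in the sham cartilage of rat 23 at 6 weeks (0.436 to 0.452%), and the chondrocyte matrix share 0.271% in the MMT synovium of rat 20 at 6 weeks (0.26 to 0.283%).

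In the TPM values, which the comparisons do not use, Mt-atp6 stood at 0 in 41 libraries and at 73.3 to 90.2% of the total in the others. The libraries at 0 numbered 0 of 32, 2 of 32, 0 of 31, 19 of 24 and 20 of 24 for plate prefixes 2 to 6, and in their counts the gene had 0.533 to 1.98% with at least 3770 counts each.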

How the results depend on the processing

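Chosen after the results were seen were the newer edgeR dispersion setting, the TPM values, and leaving out the doubted libraries (in synovium with the library with most muscle) or the latter alone. Of 276 alternative counts 230 were within 1.5 times the count given. Counts are given here as percent of the genes tested in each fit. As reported, cartilage had 1.75, 1.69 and 1.79%, meniscus 7.83, 7.06 and 5.22%, and synovium 0.00948, 2.31 and 0% at 2, 4 and 6 weeks. The time difference had 0.0834% in meniscus and 0% elsewhere, and the effect differences 4.19, 6.75 and 1.22%. Over the alternatives cartilage ran from 0.318 to 2.87%, 0.257 to 3.97% and 0.699 to 4.62%. Meniscus ran from 0.35 to 8.82%, 0.216 to 8.08% and 2.42 to 76.8%, and synovium from 0 to 0.0663%, 0 to 3.02% and 0 to 0.021%. The effect differences ran from 2.19 to 7.25%, 3.09 to 8.1% and 0.624 to 1.9%, and the sham differences from 34.1 to 61.3%, 42.2 to 67.2% and 20.3 to 37.2%. The order of these differences is meniscus and cartilage, synovium and cartilage, synovium and meniscus. Relative log expression scaling moved no median of an MMT effect by more than 0.03. The cause was not tested except where construction shows it.

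With DESeq2 the share was 2.87% in cartilage and 0.0663% in synovium at 2 weeks and 0.019% in synovium at 6 weeks. It was 0.315% and 0.00948% for the time differences of meniscus and synovium, and 1.9% for the effect difference of synovium and meniscus. With limma-voom it was 3.97% and 4.62% in cartilage at 4 and 6 weeks, 0.019% and 0% in synovium at 2 and 4 weeks, and 7.25% for the effect difference of meniscus and cartilage. Fits of the 16 libraries alone gave 1.19, 1.19 and 4.04% in cartilage, and 0 and 0.0329% in synovium at 2 and 4 weeks. With the rat as a block synovium had 0.0474% and 0.0948% at 2 and 4 weeks. Blocked values that change a call stand beside it or here, but not for all genes. With the block Wisp2 in cartilage was lost (adjusted p = 0.0651, 0.088 and 0.102). Vegfa (0.00357 and 0.00107) and Klf15 (0.0468 and 0.00442) were gained at 4 and 6 weeks. Of 357 calls of named genes over all comparisons, 322 were kept and 22 others gained. With the plate prefix as a covariate the meniscus time difference had 0.0464% and synovium at 4 weeks 0%. With the muscle covariate synovium at 4 weeks had 0.0474%. With no filter synovium had 0% and 0.39% at 2 and 4 weeks. Without rats 6 and 11 it had 0% and 1.21%, and the meniscus time difference 0.0184%. Without the low-depth library synovium at 4 weeks had 2.94%, and without the one with most muscle, alone or with the former, 0%. Of 20 calls of named genes in synovium over the 3 weeks 5% were kept without the one with most muscle alone, none of them at 4 weeks.

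On TPM values the share was 0.318% and 0.257% in cartilage at 2 and 4 weeks, and 0.35, 0.216 and 76.8% in meniscus with 0.473% for the time difference. Synovium had 0, 0 and 0.021%, and 35.5% of the calls of named genes over all comparisons were kept. Without Mt-atp6 it was 4.29% and 2.76% in meniscus at 2 and 6 weeks, 0% for its time difference, and 0.0172% and 0% in synovium at 2 and 4 weeks. Of 80 list calls 19 held with an estimated correlation, and fry called 45 lists. With the muscle covariate the muscle list in synovium at 4 weeks turned upward (adjusted p = 0.344). So did the log2 changes of Atp2a1 (0.446, adjusted p = 0.712) and Tnnt3 (0.012, adjusted p = 0.992). None of these passed, and the covariate is itself the mean of the muscle list.

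On unscaled TPM values Map1lc3b turned in meniscus at 2 weeks (-0.127). At 6 weeks Sod2 (-0.069), Htra1 (-0.59), Fstl1 (-0.74), Trpv4 (-0.24), Rgs5 (-0.76), Spp1 (-0.01), Mmp14 (-0.28), Tgfbi (-0.76), Inhba (-0.26), Pdgfrb (-0.77), Mmp2 (-0.27), Map1lc3b (-0.68), Piezo1 (-0.76), Itgb1 (-0.84) and Postn (-1.04) turned negative. So did Ctsk (-0.061), Il1b (-0.77), Mmp9 (-0.044), Cxcl12 (-0.86), Tnc (-0.20), Cdc20 (-0.072), Laptm5 (-0.81), Pdpn (-0.74), Col6a3 (-0.44), Mt-co1 (-0.92) and Mt-co2 (-0.92). There the median of all genes moved by -0.849, as Mt-atp6 takes most of the total.

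Leaving out 1 rat at a time gave 1.06 to 1.8%, 0.89 to 1.6% and 0.945 to 1.4% in cartilage, 5.41 to 7.87%, 4.55 to 6.53% and 3.35 to 5.68% in meniscus, and 0 to 0.0565%, 0 to 3.02% and 0 to 0% in synovium, at 2, 4 and 6 weeks. Of 301 calls of named genes, 215 were kept in every such fit. Meniscus had no low-depth library and no library closer to another tissue, and synovium none of the latter, so those alternatives gave no value there. Depth and group size limit small changes. A simulated 1.5-fold change was called in 18.5% of cases in cartilage, 45.5% in meniscus and 27.7% in synovium at 2 weeks, and a 4-fold change in 86.2%, 98.5% and 92.2%. These simulations held no differences in tissue make-up.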

Other observations

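The comparisons of overlap between tissues in this part were chosen after the results were seen.

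MMT moved some genes in opposite directions in cartilage and meniscus. Over the 3 weeks 19 genes rose in 1 of the tissues and fell in the other, not always at the same week, against 18.7 by chance overlap, so their number is no sign of an opposite response. Lamb3 had log2 changes of 1.88, 1.43 and 1.27 in cartilage and -1.16, -1.68 and -1.0 in meniscus at 2, 4 and 6 weeks, and passed at all but the last. F3 had 3.49, 1.25 and 1.24 in cartilage and -0.48, -0.57 and -0.96 in meniscus, and passed only at 2 weeks in cartilage and 6 weeks in meniscus. Msx1, a homeobox transcription factor of limb development, had 1.81, 0.78 and 1.15 against -0.69, -0.52 and -0.83, and passed at the same times as F3. Tnxb, a tenascin that organises collagen, had 0.39, 0.74 and 1.57 against -0.65, -0.85 and -0.53, and passed at 6 weeks in cartilage and at 2 and 4 weeks in meniscus. Mgp, an inhibitor of calcification, had 1.31, 1.22 and 1.13 in cartilage and -0.20, -0.33 and -0.02 in meniscus. The cell cycle regulator Ccnd1 had 0.64, 0.78 and 0.96 against -0.15, -0.38 and -0.28. Both passed at each week in cartilage and only at 4 weeks in meniscus.

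Shared genes were more frequent than opposite ones at each week. In meniscus and cartilage 55, 36 and 50 genes rose in both at 2, 4 and 6 weeks, against 6.94, 4.8 and 3.73 by chance overlap, and 13, 12 and 5 fell in both, against 0.88, 0.89 and 0.58. Those with opposite directions at the same week numbered 2, 5 and 1, against 5.43, 5.75 and 4.47. At 4 weeks 18 of the 32 genes higher in synovium and measured in both were also higher in meniscus, against 1.08 by chance overlap, and 11 of 180 genes lower in synovium were lower in meniscus, against 6.76.

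Over all libraries the transcripts with most counts were AY172581.24 (6.10% of counts), Sparc (2.79%), a collagen-binding glycoprotein, Col1a1 (1.6%), Prg4 (1.22%) and Col2a1 (1.01%).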
